A study of Zea mays with 8 samples.

How the data were processed

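Small RNA was profiled in 8 libraries of whole maize embryos, 1 for each of 3 hybrids and 5 inbred lines. Per the labels' protocols, total RNA was extracted with TRIzol, libraries were made with the TruSeq Small RNA kit, and gel slices of about 18 to 26 nt were recovered after PCR. The labels spell 1 line Change 7-2 where the series design has Chang 7-2, and it is called Chang 7-2 here. Each deposited file lists distinct sequences and, for each, a raw read count, without normalization; this was read from the values, which are whole numbers from 1 with a different total in each file. The submitters' processing notes name FastQC. The tool that removed adaptors, its filters and any aligner or genome build are not given in the sources used here. There was 1 library per file and nothing was pooled.

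The files hold tags of 18 to 44 nt in 5 libraries and 18 to 30 nt in the 3 libraries of the Yuyu 22 trio, and this was treated as a technical batch. It coincides with the germplasm of that trio. Total counts ranged from 9735651 to 18590068 reads per library and served as library sizes. No pair of libraries was alike within sampling noise: over the 112785 tags with a read in all 8 libraries, the chi-square per degree of freedom lay between 5.94 and 46.7 in the 28 pairs. No genome was used here, so tags were not placed on chromosomes and the planned counts of 24-nt reads in windows and near genes were not run. The reference gene table of the assembly Zm-B73-REFERENCE-NAM-5.0 was used only for names of miRNA genes. No other columns of sample values were left unused.

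Tags were assigned to 29 miRNA and trans-acting siRNA families through 51 mature sequences listed from general knowledge before the data were examined, as were the tests, the gene lists and the rule for named items. A tag of 19 to 23 nt belonged to a family if it held the 16-base core of a listed sequence (bases 3 to 18) exactly, starting at offset 0 to 4. Families were grouped in lists for phase change, developmental transcription factors, auxin, small RNA machinery, copper, phosphate and sulfate, reproductive tissue (as a marker of other tissue) and other conserved families. Structural RNA was counted as tags that are exact pieces of 5 listed sequences of 5.8S rRNA, 5S rRNA, tRNA-Gly, tRNA-Ala and tRNA-Asp.

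Shares of size classes from 20 to 24 nt and of structural RNA were compared between hybrids and inbred lines by a two-sided exact permutation test of the difference of means over the 56 splits of 8 libraries, with Benjamini-Hochberg adjustment. Families and tags were tested with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3 after filterByExpr, which left 25 families and 142313 tags. Family counts were scaled by all reads of the library and tag counts by TMM factors. The 2-group fit compared hybrids with inbred lines. The mid-parent fit had 1 term for each of the 5 inbred lines, gave each hybrid equal parts of its parents on the log scale and tested a term common to the 3 hybrids, with 2 residual degrees of freedom. An adjusted p under 0.05 was the threshold. Gene lists with at least 2 measured families, 6 in all, were tested with fry of limma 3.58.1 on log2 CPM with a prior count of 2. fry tests whether the families of a list move, on balance, one way and does not compare them with other families. As no label says that a variety was sampled more than once, the p-values measure the spread between single libraries of different genotypes.

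Within a trio no test is possible, and levels have exact Poisson 95% intervals and shares exact (Clopper-Pearson) binomial 95% intervals. Intervals of ratios came from 4000 draws of gamma-distributed rates (count plus 0.5). All cover counting error only. A count of 0 allows up to 3 reads per library. Parent-specific and hybrid-only tags were counted after random thinning of every library to 9735651 reads, at a minimum of 5 RPM (reads scaled to the library total). The named families are those past the threshold in either fit, the 10 most abundant, and those in each trio with a log2 over the mid-parent of at least 1 either way and at least 100 reads on the higher side. The named tags are, of those past the threshold with a mean of at least 5 CPM and the same direction against the mid-parent in all 3 trios, the 5 with the largest rise and the 5 with the largest fall. miR1432, miR164 and other families named outside this rule were chosen after their values were seen or as members of a list.

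Alternatives tried included other scalings, DESeq2 1.42.0, other filters, other matching, distinct tags in place of reads and leaving out each library in turn. Chosen after seeing the files were batch as a term, the 5 libraries with tags up to 44 nt alone, an arithmetic mid-parent in limma (log2 after adding 0.5 RPM), 21-nt or 22-nt tags alone for parental tags, a free first base for structural RNA, and an unweighted trimmed mean as scaling. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 was used for counting and exact tests. The tests were tried on simulated data with known changes. Apart from these changes, each simulated tag or family had the same mean level in all libraries, without differences between genotypes or batches. For 20000 simulated tags with 200 changed at a dispersion of 0.1, the 2-group test recovered 71.0% of 4-fold and 93.5% of 8-fold changes, with 4.70% and 3.11% false among the calls. The mid-parent test recovered 66.5% and 88.5%, with 2.92% and 5.85% false. The arithmetic mid-parent test recovered 76.0% and 83.0%, with 9.52% and 11.7% false. For 25 simulated families in 50 data sets at a dispersion of 0.2, the 2-group test recovered 86% and the mid-parent test 64% of 4-fold changes, and fry called the changed list in 100% of the sets.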

Results

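Small RNAs of whole embryos from maize (Zea mays) seeds soaked for 24 hours at 26 °C were sequenced in 8 varieties: 3 commercial hybrids known for strong heterosis and the 5 inbred lines that are their parents. The crosses, paternal line first, were Chang 7-2 × Zheng 58 for Zhengdan 958, Chang 7-2 × 9058 for Lingdan 20, and 87-1 × Zong 3 for Yuyu 22. Each variety had 1 library, so the hybrid group held 3 libraries and the inbred group 5, and the spread within a group was a spread between genotypes. The hybrids descend from the inbred lines and Chang 7-2 entered 2 crosses, so the groups were not independent. Libraries held 9735651 reads (87-1) to 18590068 reads (9058). Across the 8 libraries there were 24434689 distinct sequences of 18 to 30 nt, called tags here, of which 78.4% occurred in 1 library and 112785 occurred in all 8. The libraries of the Yuyu 22 trio had no tag longer than 30 nt, whereas the other 5 had tags up to 44 nt; this batch difference lay between trios and not within any of them.

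The first comparison asked whether hybrid embryos held another mix of small RNA lengths than inbred embryos. Embryos of all 8 varieties had their largest share of reads at 24 nt, the length of heterochromatic siRNAs, except those of 9058, in which 22-nt reads led. The 24-nt class made up 35.3% ± 8.65 of the reads in hybrids (SD, n = 3) and 31.9% ± 7.33 in inbred lines (SD, n = 5). The 22-nt class, which is abundant in maize, made up 24.9% ± 4.48 and 26.7% ± 5.65, and the 21-nt class, which holds most miRNAs, 15.1% ± 1.48 and 17.1% ± 2.55. The 20-nt shares were 8.44% ± 2.85 and 8.35% ± 2.44, and the 23-nt shares 5.47% ± 1.12 and 5.40% ± 0.692. None of the 5 lengths differed by more than the spread between varieties (two-sided exact permutation test over 56 splits, lowest exact p = 0.25 at 21 nt, Benjamini-Hochberg adjusted p = 0.952; the smallest exact p this design allows is 0.0357).

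**Figure D1:**
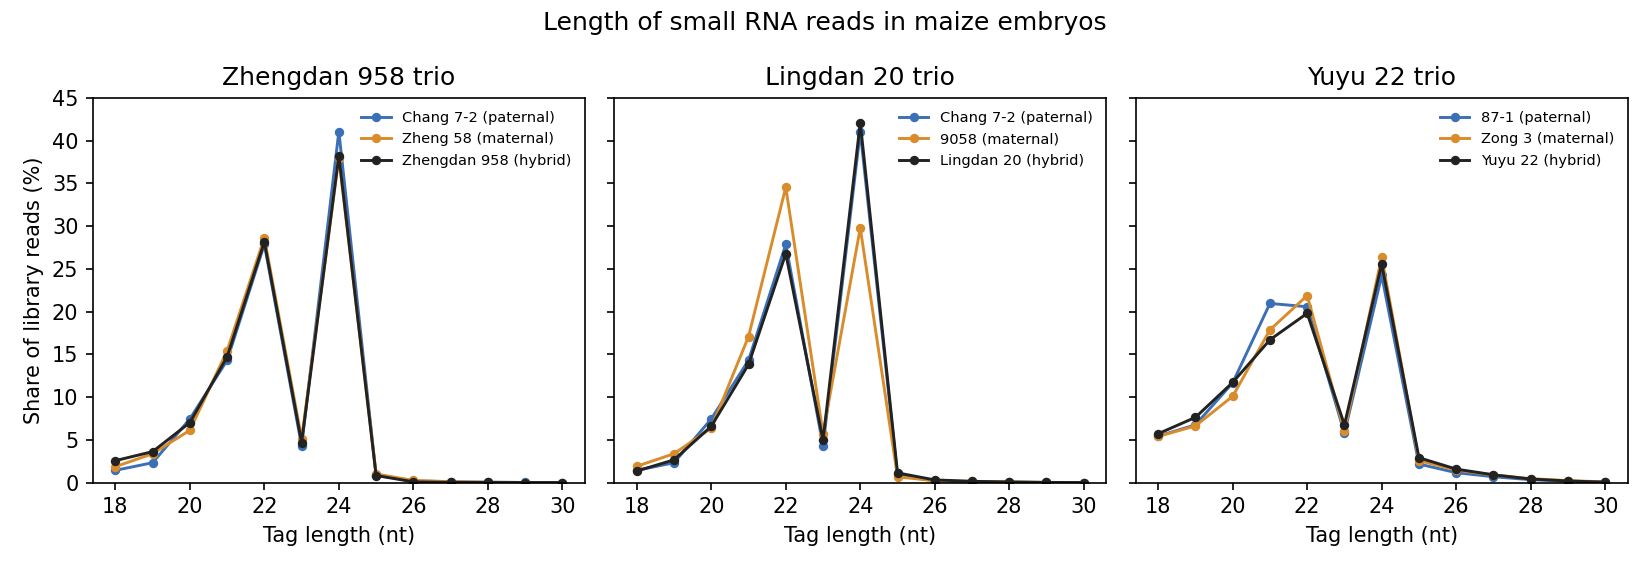
Share of library reads (y axis, %) by tag length (x axis, nt) in 3 panels, 1 for each trio, with lines for the paternal line, the maternal line and the hybrid; there is 1 library per variety. The 24-nt share lies between 24.2% and 26.4% in the Yuyu 22 trio and between 29.8% and 42.1% in the other 5 libraries.

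The direction of the 24-nt difference was not shared by the trios. Lingdan 20 had 42.1% of its reads at 24 nt against 41.1% in Chang 7-2 and 29.8% in 9058, which placed it 6.69 percentage points above its mid-parent. Zhengdan 958, at 38.3%, lay 1.28 points below its mid-parent (a difference of -1.28), and Yuyu 22, at 25.6%, lay 0.282 points above. The 21-nt share was below the mid-parent in all 3 hybrids, with differences of -0.139 points in Zhengdan 958, -1.88 in Lingdan 20 and -2.71 in Yuyu 22. So was the 22-nt share, with differences of -0.0966, -4.43 and -1.42 points. The exact binomial 95% interval of the 24-nt share ran from 42.10% to 42.15% in Lingdan 20. Such intervals cover counting error only, since reads amplified by PCR are not independent molecules, and a single trio has no replicate check. Within the 5 libraries with tags up to 44 nt, hybrids minus inbred lines gave 3.90 points at 24 nt, -2.88 at 22 nt, -1.33 at 21 nt, -0.234 at 23 nt and 0.153 at 20 nt. Their lowest adjusted exact p was 0.667, where 2 hybrids against 3 inbred lines cannot go below an exact p of 0.2. The other 3 libraries hold 1 hybrid and 2 inbred lines, too few for a test, and their difference is that of the Yuyu 22 trio.

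Known miRNA families took 6.25% (Zheng 58) to 13.9% (87-1) of the reads. The share was 7.29% ± 0.546 in hybrids (SD, n = 3) and 8.80% ± 3.10 in inbred lines (SD, n = 5; two-sided exact permutation p = 0.536). Embryo miRNA was dominated by 4 families. miR156, which maintains the juvenile phase by repressing SPL transcription factors, averaged 31785 RPM (the read count of the family scaled to the reads of its library) over the 8 libraries, and 90.4% of its reads were the tag TGACAGAAGAGAGTGAGCAC. miR166, which targets HD-ZIP III transcription factors, averaged 21545, mostly as TCGGACCAGGCTTCATTCCCC. miR528, a monocot miRNA with targets among copper proteins, averaged 17812, mostly as TGGAAGGGGCATGCAGAGGAG. The reference gene table of the B73 assembly Zm-B73-REFERENCE-NAM-5.0 lists 2 genes for it, whose reads were not separated. miR168, which targets ARGONAUTE mRNA, averaged 8460. The order of these 4 varied by library: miR528 led in 87-1, with 57562 RPM against 45816 of miR156, miR166 led in Zheng 58, with 23093 against 20265, and miR528 was below miR156, miR166 and miR168 in Zhengdan 958, Lingdan 20 and Zheng 58. The rest of the 10 most abundant families were miR167, with targets among auxin response factors, at 1740 RPM, tasiR-ARF, a trans-acting siRNA against auxin response factors, at 337, miR169 at 161, miR827 at 116, miR444 (60.5 in hybrids and 83.7 in inbred lines) and miR408 at 55.1. miR164, which targets NAC transcription factors, averaged 39.2, from 4264 reads in all; with 1 mismatch allowed it had 183635 reads, so its level depends on the matching. Other families have few or no reads identical to the sequence listed for them and were counted through shifted, longer or variant tags that hold its core. tasiR-ARF had 18 identical reads of 41195, miR319 330 of 4601 and miR172 105 of 1421, while miR393, with 565 reads, and miR1432, with 237, had 0.

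Hybrids as a group were compared with inbred lines to find families whose level differs with hybrid status. Of the 25 families with enough reads, none passed an adjusted p of 0.05 in edgeR's quasi-likelihood test, and 1 had an unadjusted p under 0.05. DESeq2 also called 0, with 2 at an unadjusted p under 0.05. miR528 averaged 9348 ± 10021 RPM in hybrids (SD, n = 3) and 22890 ± 20868 in inbred lines (SD, n = 5), a log2 difference of -1.29 (SE 0.88, edgeR adjusted p = 0.709). The family with the highest mean, miR156, stood at 30345 ± 1671 and 32649 ± 11513 RPM (log2 -0.11, SE 0.32, edgeR adjusted p = 0.974). The miR156 estimate was positive with TMM factors (0.061), with miRNA reads as library size (0.16) and in DESeq2 (0.29). miR529, which shares SPL targets with miR156, had the smallest p of the 25, with 5.47 ± 2.70 against 16.9 ± 9.04 RPM (log2 -1.63, SE 0.64, edgeR adjusted p = 0.709). tasiR-ARF was one of 5 families with a positive estimate, at 388 ± 53.3 in hybrids and 307 ± 53.3 in inbred lines. Estimates were negative for 20 of the 25 families, with a median of -0.31. The median was -0.13 with TMM factors over the families, -0.17 with miRNA reads as library size and -0.51 with 24-nt reads. In DESeq2 it was 0.028, so the size and the sign of this general shift depend on the scaling. In 50 simulated data sets with the 4 copper families lowered 4-fold, the 2-group test recovered 86% of them. The simulated libraries had no differences between genotypes or batches, so recovery in the real libraries is not known. There the SEs of these families were 0.88 for miR528, 0.70 for miR408, 0.65 for miR398 and 1.10 for miR397.

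The pedigree gives a second test, in which each hybrid is set against the mean of its own parents on the log scale. No family passed an adjusted p of 0.05 in edgeR's quasi-likelihood test, 4 had an unadjusted p under 0.05, and DESeq2 called 0 with 3 at an unadjusted p under 0.05. miR528 missed the threshold, with a log2 difference of -1.25 (SE 0.23, 2.38-fold lower, edgeR adjusted p = 0.052). It was below both parents in each of the 3 trios. miR528 was also the 1 family of 25 called between batches in a fit with hybrid status as a further term, with a log2 of -2.23 for the libraries with tags up to 44 nt over those of the Yuyu 22 trio (edgeR adjusted p = 0.00836). In that fit 4 more families were at an adjusted p of 0.0549, and without the hybrid term edgeR called 5 families between the batches. The estimate ran from -1.47 to -0.87 over 16 alternative settings. The adjusted p ranged from 0.00986 to 0.472, and 3 of the settings brought it under 0.05. Among them, with only tags identical to the listed sequence, edgeR's adjusted p was 0.00986. With an arithmetic mid-parent, an alternative added after the data were seen, limma called 3 families, miR528, miR529 and miR1432, each at an adjusted p of 0.0447. miR1432 had no read identical to its listed sequence. This limma test takes the 3 trios as independent, although some of the hybrids share a parental library, so its p-values may be too small. On simulated tags, 9.52% of its calls were false at 4-fold changes and 11.7% at 8-fold changes. With 1 mismatch allowed edgeR's adjusted p of miR528 was 0.042. Estimates for the next families in edgeR's test were -1.17 for miR1432 (SE 0.45), -1.15 for miR529 (SE 0.45), -0.90 for miR408 (SE 0.35) and -0.82 for miR398 (SE 0.34), each with an adjusted p of 0.285. The median over the 25 families was -0.21. It moved to 0.035 when libraries were scaled by their miRNA reads, so these values are best read relative to it. In simulated data with 4 families lowered 4-fold, without differences between genotypes or batches, this test recovered 64%.

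Gene lists fixed beforehand grouped the families by function. The copper list, whose members target copper proteins such as laccases, plantacyanins and superoxide dismutases, had 4 measured families, all with negative estimates against inbred lines and a mean log2 of -0.77. It did not pass limma's fry (adjusted p = 0.425 over 6 lists). With each library left out in turn, the mean of this list lay between -1.13 (without Zong 3) and -0.38 (without 87-1). Against the mid-parent, its mean was also -0.77, with estimates of -1.25 for miR528, -0.90 for miR408, -0.82 for miR398 and 0.023 for miR397 (fry adjusted p = 0.063). The miR397 value was -0.97 with the arithmetic mid-parent and -0.048 with 24-nt reads as library size. Adjusted over the list alone, 1 of the 4 copper families, miR528, had an adjusted p under 0.05 in edgeR's mid-parent test (0.00832). No family of the other lists did in either test adjusted over the list alone. The phase change list (miR156, miR529 and miR172) had a mean of -0.49 and a median of -0.034 against inbred lines (fry adjusted p = 0.243). The list of developmental transcription factor regulators, with 8 families, had a mean of -0.12 (fry adjusted p = 0.464), and the auxin list, with 5 families, a mean of -0.14 (fry adjusted p = 0.603). Means of the latter lists turned positive with TMM factors over the families (0.087 and 0.058). miR162 and miR168, which target the small RNA machinery, had a mean of -0.44 (fry adjusted p = 0.243), and the pair of other conserved families, miR394 and miR1432, a mean of -0.85 (fry adjusted p = 0.243). No list had an adjusted p under 0.05 in limma's camera with the preset correlation (lowest adjusted p = 0.577) or with an estimated correlation (lowest adjusted p = 0.667). Of the phosphate and sulfate list only miR827 was measured. miR2118 and miR2275, the triggers of phased siRNAs in anthers and used here as markers of reproductive tissue, were at 0 reads in all 5 inbred lines. A count of 0 allows up to 3 reads, which is 0.161 RPM in 9058 and 0.308 RPM in 87-1. miR2118 was at 0 in the hybrids too, and miR2275 had 1 read, in Lingdan 20.

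Within each trio, families were named where the hybrid departed from the arithmetic mid-parent by a factor of at least 2 (a log2 of 1) with at least 100 reads. In Zhengdan 958 these were 4 families, all lower than the mid-parent: miR408 at log2 -1.40, miR528 at -1.37, miR398 at -1.34 and miR827 at -1.20. miR528 stood at 3293 RPM against 12057 in Chang 7-2 and 4957 in Zheng 58. With the geometric mid-parent, 2 families were lower and 1, miR394, was higher; with TMM factors over the families 3 were lower. In Lingdan 20, miR528 at -1.73, miR529 at -1.70 and miR160 at -1.17 were lower, while miR319, which targets TCP transcription factors, was higher at 1.95 and miR393, which targets auxin receptors, at 1.09. Lingdan 20 had 3836 RPM of miR528 against 12057 in Chang 7-2 and 13482 in 9058, and 58.9 of miR319 against 13.7 and 16.8. With identical tags alone miR319 was at 0.12 in Lingdan 20, miR393 had no reads, and 0 families were higher. The miR319 reads were mostly TTGGACTGAAGGGTGCTCCCT, the listed sequence with 1 more base, which had 50.7 RPM in Lingdan 20 against 10.3 and 11.6. In Yuyu 22 there were 6, all lower: miR397 at -2.25, miR529 at -1.95, miR408 at -1.87, miR319 at -1.28, miR398 at -1.07 and miR528 at -1.01. Only 3 were lower with the geometric mid-parent, and 3 with TMM factors over the families. miR528 in Yuyu 22 was at -0.53 with these factors and at -0.42 with miRNA reads as library size. Its miR528 level was 20914 RPM against 57562 in 87-1 and 26392 in Zong 3. Over the geometric mean of the parents, miR397 in Yuyu 22 was instead higher, at 0.55. Counting intervals of these log2 values were wide for families with few reads, as for miR160 in Lingdan 20 (-1.73 to -0.67). Exact Poisson intervals of the levels cover counting error only, and a difference in 1 trio has no replicate check.

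**Figure D2:**
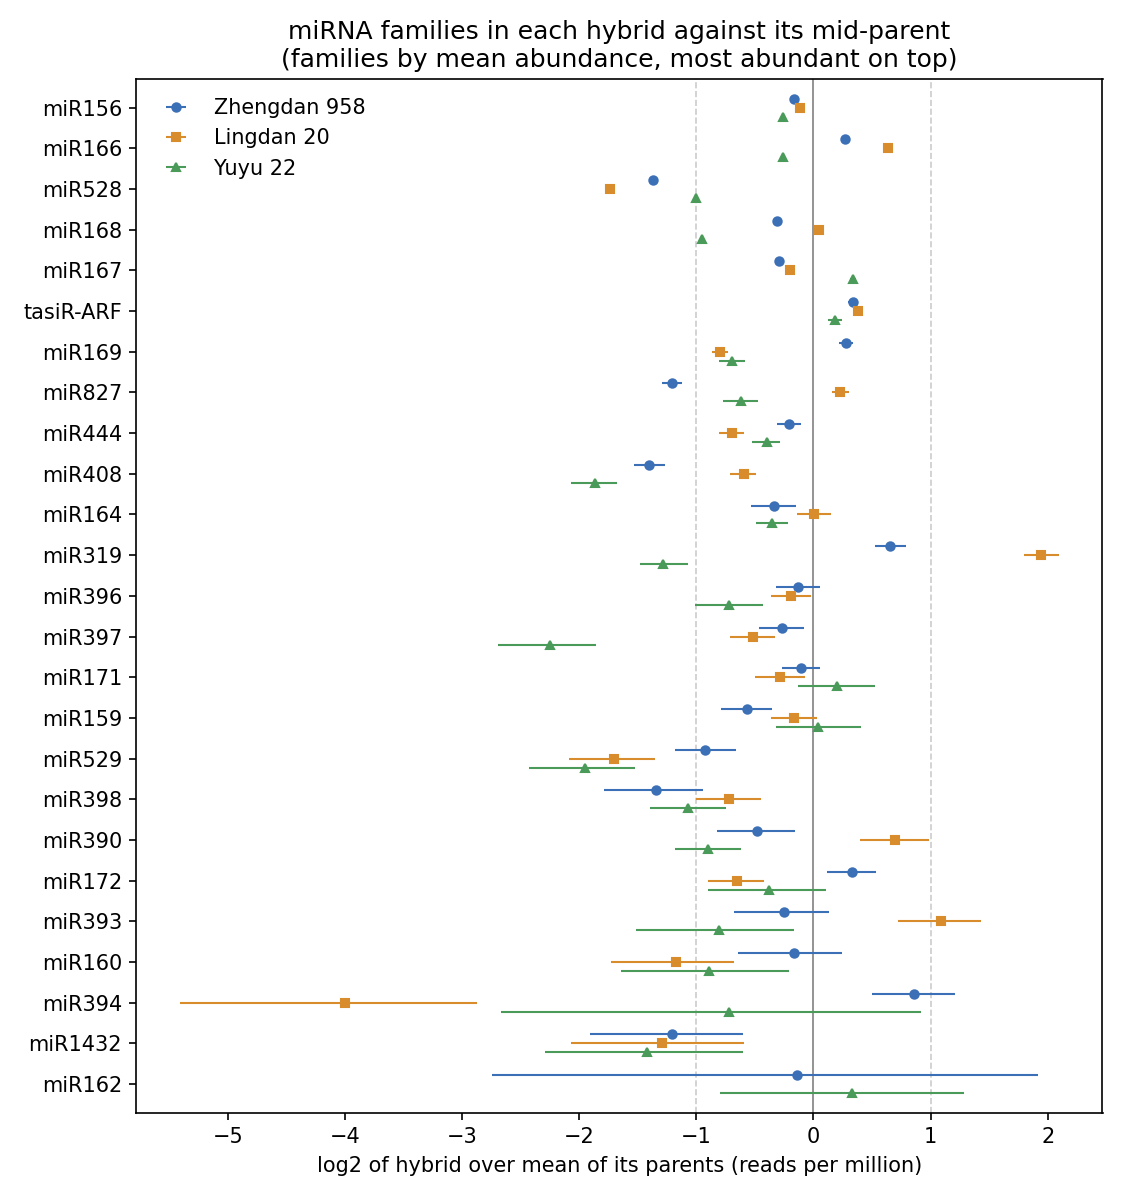
log2 of each hybrid over the mean of its parents in RPM (x axis) for the 25 tested families (y axis, most abundant on top), with 1 symbol per trio and 95% counting intervals as bars; a family without a read in a hybrid has no symbol. miR528 lies at -1.37, -1.73 and -1.01 in the 3 trios, and miR319 at 1.95 in Lingdan 20 and -1.28 in Yuyu 22.

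The parents of each cross also differed from each other. Of the families with at least 100 reads, the parents of Zhengdan 958 differed by a factor of 2 or more in 12 of 22, those of Lingdan 20 in 7 of 22 and those of Yuyu 22 in 6 of 18. miR827, which responds to phosphate supply, had 43.0 RPM in Chang 7-2 and 303 in Zheng 58. miR397 had 43.7 in 87-1 and 0.228, from 3 reads, in Zong 3. miR408 was at 132 in Chang 7-2, 25.7 in Zheng 58 and 27.5 in 9058. The hybrid level lay between those of its parents for 10 of 22 families in Zhengdan 958, 10 of 22 in Lingdan 20 and 7 of 18 in Yuyu 22. With levels scaled by all reads, the families below both parents in all 3 trios were miR528, miR444, miR160 and miR1432, and no family was above both in all 3. For all but miR528 this rests in part on differences within counting error. miR160 had 60 reads in each library of the Zhengdan 958 trio, and miR1432 had 18 in Lingdan 20 against 23 in 9058. The 95% interval of miR444 in Zhengdan 958 (57.3 to 64.5 RPM) overlapped that in Zheng 58 (63.8 to 72.0). miR1432 had under 100 reads in every library.

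Single tags were then compared, to search for small RNAs outside the known families. Of 142313 tags tested, edgeR's quasi-likelihood test called 0 between hybrids and inbred lines, with 265 at an unadjusted p under 0.05, which is 0.186% of the tags. DESeq2 called 0 with 733 at an unadjusted p under 0.05. On simulated tags this test recovered 71.0% of 4-fold and 93.5% of 8-fold changes at a dispersion of 0.1. Those tags had no differences between genotypes or batches, so recovery in the real libraries is not known. The test against the log-scale mid-parent called 12879 tags higher and 125 lower, and DESeq2 called 2168 and 196. Of the tags called higher, 49.2% were 22 nt and 36.2% were 24 nt long, against 31.2% and 39.9% of the tested tags. No read in at least 1 parent was found for 96.0% of them, against 53.5% of the tested tags. Their median log2 over the arithmetic mean of the parents was only 0.20, against 0.052 for all tested tags. Limma on the arithmetic mid-parent called 0 tags, with 2973 at an unadjusted p under 0.05. With tags that had a read in every library, edgeR called 21 higher and 1 lower out of 62613, and with a minimum of 10 CPM in 3 libraries it called 0 of 9620, with 1047 at an unadjusted p under 0.05. The counts of edgeR fell when a library was left out, but such a fit loses more than that library. A trio without its hybrid or a parent says nothing of the common hybrid term. Leaving out Chang 7-2 therefore leaves only the Yuyu 22 trio to inform this term, and the lower counts cannot be laid to single libraries. Without Chang 7-2 there were 76 higher and 1 lower, without Zheng 58 3825 and 49, without Zhengdan 958 3742 and 51, without 9058 5336 and 33, and without Lingdan 20 6051 and 42. Without 87-1 there were 8969 and 67, without Zong 3 9497 and 66, and without Yuyu 22 9484 and 73.

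Of the tags called lower, 47.2% were 21 nt and 3.2% were 24 nt, and their median log2 over the arithmetic mid-parent was -1.59. The largest falls among the tags with a mean of at least 5 CPM were those of an overlapping pair. GTCCCCTTCGTCTAGCGGTTAG had 540 reads in Chang 7-2, 267 in Zheng 58 and 220 in 9058, but 2 in Zhengdan 958 and 13 in Lingdan 20 (log2 -5.59, SE 0.88, edgeR adjusted p = 0.00015). It had 1 read or none in the Yuyu 22 trio. GTCCCCTTCGTCTAGCGGTTA, which lacks its last base, had a log2 of -3.84 (SE 0.79, edgeR adjusted p = 0.00183). Smaller falls were those of GTAGGGAACTGCCAGGCAT at -2.14, AATAGAACTGTGCAGATGCTGG at -2.11 and AGAACTGTGCAGATGCTGGTCT at -2.05. The last 2 of these also overlap. AATAGAACTGTGCAGATGCTGG had 901 reads in 9058 and 460 in Zong 3 but 103 in Lingdan 20 and 8 in Yuyu 22. The largest rises were those of TCGATAGTAACTGGGATGCGCT (log2 8.30), CCATAATTCAGACTGTTGGCAG (7.91), ATGCCTGTAGAACAAAATGGAGGC (6.31), TGAGATCAGTCAGAGGCAGCAA (5.99) and CGATGGTTAAAGAGAATGACGC (5.30), each with a parent at 0 reads, so that these fitted values are no bounds. CGATGGTTAAAGAGAATGACGC had 326 reads in Chang 7-2, 0 in Zheng 58 and 0 in 9058, and 315 and 310 in their hybrids. None of the 10 tags had an adjusted p under 0.05 with the arithmetic mid-parent. The 10 tags were not compared with structural RNA beyond the 5 listed sequences, so pieces of other such RNA may be among them.

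Tags found in only 1 parent of a cross show which parental small RNAs the hybrid embryo holds. After every library was thinned to 9735651 reads, tags with at least 5 RPM in 1 parent and 0 reads in the other numbered 3587 for Chang 7-2 against Zheng 58, 3088 for Zheng 58 against Chang 7-2, 3369 for Chang 7-2 against 9058, 3828 for 9058 against Chang 7-2, 1334 for 87-1 and 1892 for Zong 3. The trio's own hybrid had at least 1 read for 96.8% (87-1 tags in Yuyu 22, exact binomial 95% interval 95.7% to 97.7%) to 99.9% (Zheng 58 tags in Zhengdan 958, lower bound 99.8%) of them. With 21-nt tags alone the 87-1 share in Yuyu 22 was 89.3% (84.6% to 92.9%). Hybrids not descended from that parent had a read for 35.6% to 72.9%. Only Zheng 58 tags in Lingdan 20 (62.0%) and 9058 tags in Zhengdan 958 (72.9%) were compared within a batch. Of the Chang 7-2 tags missing in Zheng 58, 98.8% had a read in Zhengdan 958, 99.7% in Lingdan 20, the other hybrid of that line, and 35.7% in Yuyu 22. The summed level of these tags in the own hybrid was 41.1% of the parental level for Chang 7-2 and 59.6% for Zheng 58 in Zhengdan 958. In Lingdan 20 it was 157506 of 393646 reads for Chang 7-2 and 33.5% for 9058, and in Yuyu 22 33.2% for 87-1 and 44.5% for Zong 3. For the Yuyu 22 parents this level was no lower in hybrids not descended from them: 87-1 tags reached 43.8% in Zhengdan 958 and 41.7% in Lingdan 20, and Zong 3 tags 49.3% and 46.4%. These summed levels therefore do not measure what Yuyu 22 received from each parent. For the parents of the other trios the level in hybrids not descended from them was 6.08% to 27.9%. With 24-nt tags alone the levels in Yuyu 22 were 42.1% for 87-1 and 42.6% for Zong 3, and again no clearer: hybrids not descended from these lines reached 41.0% and 51.9% for 87-1 tags and 39.96% and 45.5% for Zong 3 tags.

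**Figure D3:**
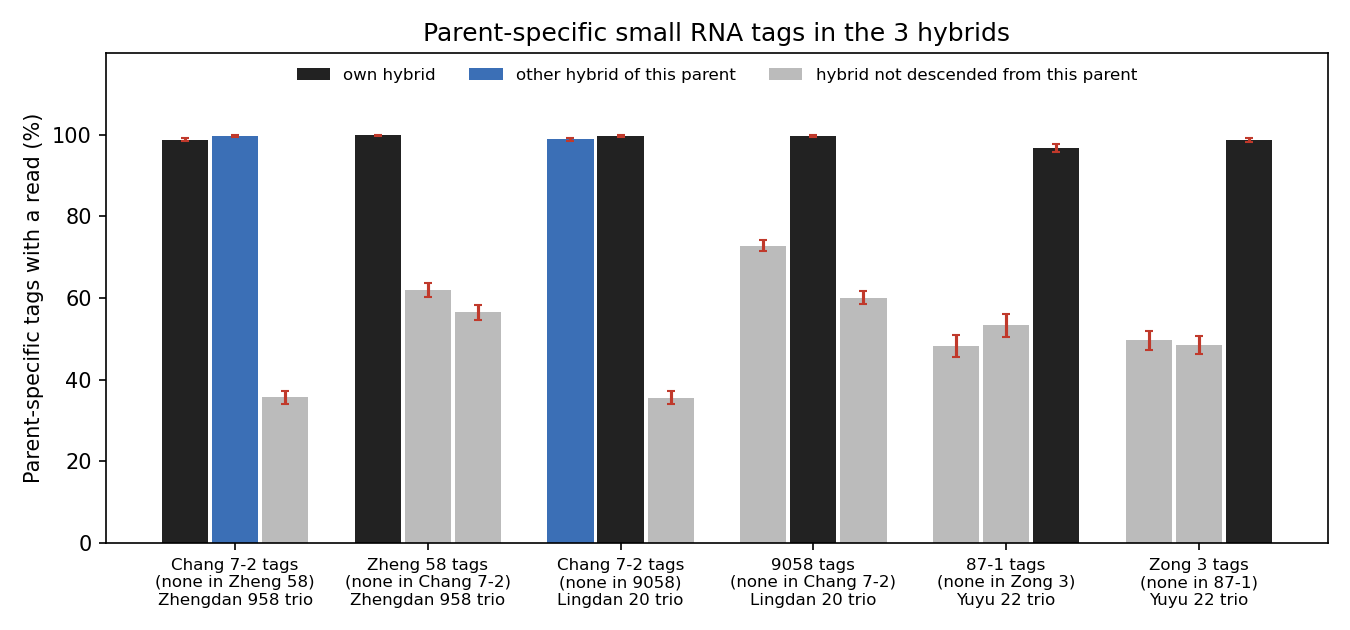
Share of parent-specific tags with at least 1 read (y axis, %) in each of the 3 hybrid libraries, for 6 sets of tags (x axis: the parent that has the tags, the parent without them, and the trio); black bars are the trio's own hybrid, blue bars the other hybrid of Chang 7-2, grey bars hybrids without that parent, and red lines exact binomial 95% intervals. Own hybrids lie between 96.8% and 99.9% and hybrids without that parent between 35.6% and 72.9%.

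Few tags were present in a hybrid and missing in both its parents. Of the tags with at least 5 RPM, 8 of 14941 (0.0535%, exact binomial 95% interval 0.0231% to 0.105%) in Zhengdan 958, 6 of 13535 (0.0443%, 0.0163% to 0.0965%) in Lingdan 20 and 13 of 14787 (0.0879%, 0.0468% to 0.150%) in Yuyu 22 had no read in either parent. Against the parents of another trio, the same share was 2.07% to 15.7%. The 2.07% of Lingdan 20 and 3.56% of Zhengdan 958 are against each other's parents, which include their common parent Chang 7-2. The others, from 8.34% up, compare libraries of different batches. No background was thus both unrelated and within a batch. All 6 of Lingdan 20 were 21 nt long, and 10 of the 13 of Yuyu 22 were 22 nt. Of those 13, 7 stood at 5 RPM or more in 9058, an inbred line that is no parent of Yuyu 22.

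Pieces of ribosomal and transfer RNA were measured as a sign of RNA quality. The 5 chosen RNAs together gave 3.03% ± 1.62 of the reads in hybrids (SD, n = 3) and 2.75% ± 1.19 in inbred lines (SD, n = 5), with no difference beyond the spread (two-sided exact permutation p = 0.714, adjusted p = 0.857). 5.8S rRNA gave 1.15% ± 0.827 and 0.956% ± 0.720, 5S rRNA 0.282% ± 0.316 and 0.246% ± 0.198, tRNA-Ala 1.39% ± 0.645 and 1.34% ± 0.434, tRNA-Gly 0.0799% ± 0.0534 and 0.0648% ± 0.0543, and tRNA-Asp 0.130% ± 0.115 and 0.142% ± 0.144. Such pieces did differ by batch, in ranges that did not overlap. The 3 libraries of the Yuyu 22 trio had 4.29% ± 0.619 of such pieces (SD, n = 3) and the other 5 had 1.99% ± 0.306 (SD, n = 5). 5.8S rRNA was at 1.84% ± 0.372 and 0.543% ± 0.141, whereas tRNA-Asp was at 0.00415% ± 0.00253 and 0.217% ± 0.0780, 52.4 times higher in the libraries with tags up to 44 nt.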

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

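Tests chosen only after the result was seen were the arithmetic mid-parent and the simulated hybrids, the other splits and arrangements, the count of trios and scalings with miR528 below both parents, the unweighted trimmed mean, batch as a term, the most frequent miR319 tag and the levels of 6 tags relative to Lingdan 20; matching by identical tags and the other scalings were fixed beforehand.

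Among the inbred lines, 2 of 41 sets of values had 1 line far from the other 4, and chance alone gives about 1 in 20. miR395 stood at 0.456 RPM in the highest line and 0.0589 in the next (gap over range 0.871), and miR399 at 0.308 and 0.0760 (0.753). Both families were below the abundance filter. miR319 departed from the mid-parent in opposite ways in Lingdan 20 (log2 1.95) and Yuyu 22 (log2 -1.28), a span of 3.23, and with 1 library per variety the difference was not tested. This rests on the matching: with tags identical to the listed sequence, 330 of 4601 reads, the values were 0.12 and -0.76. The most frequent miR319 tag, the listed sequence with 1 more base, had 50.7 RPM in Lingdan 20 against 10.3 and 11.6 in its parents, and 15.8 in Yuyu 22 against 41.5 and 40.9. Tags over 30 nt, which entered only the library totals, held 7133 reads in 5 libraries and 0 in the 3 libraries of the Yuyu 22 trio.

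The excess of tags above the log-scale mid-parent was 12879 higher against 125 lower. Chance was not excluded for the count: of 40 arrangements of the libraries in the pedigree, 3 gave as many tags called higher, the real one included, and the highest of the others gave 16790, whereas the smallest p of the real arrangement in edgeR, a negative log10 of 10.2, was reached by none of the others (highest 5.93). These arrangements were drawn over all libraries and could mix batches within a trio, which the real pedigree does not. Their values can therefore reflect batch, so this comparison does not measure chance alone. The tags called higher lay close to the plain mean of the parents, with a median log2 of 0.20 over the arithmetic mid-parent. Hybrids simulated at exactly the mean of their real parents gave 12827 tags called higher and 0 lower. This was a single simulated set with a chosen noise level that was not varied. The closeness of 12827 to 12879 therefore carries no weight by itself. A log-scale mid-parent of tags that are missing in a parent is therefore a likely source of most of the excess, and it leaves the 125 tags called lower open.

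miR528 lay below both parents in all 3 hybrids, and a difference between batches of longer and shorter tags was excluded as the cause, since every trio lies within 1 batch and the hybrid difference with batch as a term was -1.33 (log2, SE 0.41). Scaling stays open: the hybrid was below both parents in 12 of 12 comparisons of 3 trios and 4 scalings, edgeR's TMM factors among them. An unweighted trimmed mean, which was computed before the TMM factors and then replaced by them, put Yuyu 22 at -0.22 and no longer below both parents. Chance stays open as well. Over 180 rearrangements of the pedigree within batches the exact p of miR528 was 0.0444 (two-sided), and the adjusted exact p over 25 families was 0.556. Swapping the hybrids that share a parent leaves the mean over the trios unchanged, so every arrangement has an equal twin. The exact p can therefore not go below 0.0222, the value of miR1432, and no single family could have passed. An effect of the hybrid state may account for the pattern too and was not tested apart from these.

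The Yuyu 22 tags that both its parents lack and 9058 holds could be reads carried over from another library. Only 66 of 716 tags abundant in 9058 and Lingdan 20 and missing in 87-1 and Zong 3 (9.22%) had a read in Yuyu 22, close to the 7.01% among tags of Chang 7-2 and Zhengdan 958, so a general carry-over was excluded. The 6 of them at 5 RPM or more in Yuyu 22 reached 0.475 to 1.27 times their Lingdan 20 level. Seed of 87-1 or Zong 3 that differed from the sequenced plants stays open and was not tested.

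Counts of 0 calls cannot be set against other splits, since every split gives at least 0: this held in 56 of 56 splits for tags and 56 of 56 for families between hybrids and inbred lines, and in 100 of 100 arrangements for families against the mid-parent. Counts at an unadjusted p under 0.05 in edgeR were compared instead. For tags, 47 of 56 splits of 5 and 3 libraries gave as many as the real 265, and for families 38 of 56 gave as many as the real 1, so chance was not excluded for either. Against the mid-parent, 12 of 100 arrangements gave as many families as the real 4, the highest other giving 10, and chance was not excluded. These arrangements, too, were drawn without regard to batch and do not measure chance alone. The split with the most calls sets the 3 libraries of the Yuyu 22 trio against the other 5. Fitted without a hybrid term, it called 39809 tags and 5 families (1 family with that term), with 63845 tags and 9 families at an unadjusted p under 0.05, and points to a structure of the samples by batch or germplasm, which the design does not separate. With batch as a term edgeR called 0 tags between hybrids and inbred lines, with 744 at an unadjusted p under 0.05. The highest count of families called in another arrangement against the mid-parent was 4.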

How the results depend on the processing

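Chosen after seeing the data were batch as a term, the libraries with tags up to 44 nt alone, the arithmetic mid-parent, the 21-nt and 22-nt tags alone, the free first base of structural RNA and the unweighted trimmed mean. Of 1105 alternative values for 109 results, 899 stayed the same, 45 no longer passed, 8 newly passed, 76 moved and 77 turned their sign. A tested value stayed the same if it kept its direction and its side of the threshold. A count did so if it stayed within a set factor. Other values did so if they stayed within their counting interval or a small set margin. A count that fell to none was taken as no longer passing, and one that rose from none as newly passing. Where no other reason is given, the cause was not tested. The 24-nt windows and the position of 24-nt reads relative to genes, with their alternatives, were not run, as no genome was used here. The 3 libraries with tags up to 30 nt were not tested alone, since they hold 1 hybrid. Replicate numbers are only an order of samples, so no fit used them as a block. Hybrids were matched to their parents through the pedigree, in the mid-parent comparisons. Depth limits families with few reads, such as miR162 with 41 reads in all.

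Signs turned mostly for values near 0. Against inbred lines, miR156 was at 0.061 with TMM factors, 0.16 with miRNA reads as library size, 0.29 in DESeq2 and 0.023 in the libraries with tags up to 44 nt. miR167 was at 0.14 with TMM factors and 0.31 in DESeq2. With 24-nt reads as library size, miR319 was at -0.10, miR166 at -0.015 and miR393 at -0.22. miR319 was at -0.22 with identical tags and miR393 at -0.10 with batch as a term. Against the mid-parent, miR156 was at 0.050, 0.11 and 0.25 and miR167 at 0.17, 0.23 and 0.37 with TMM factors, with miRNA reads and in DESeq2. miR167 was at 0.095 with identical tags, and miR169 at 0.030 in DESeq2. miR397 was at -0.048 with 24-nt reads as library size and -0.97 with the arithmetic mid-parent, and miR827 at -0.53 with the latter. In Yuyu 22 miR397 was at 0.55 over the geometric mid-parent. The mean of the auxin list was 0.058 and that of the developmental list 0.087 with TMM factors.

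Families called against the mid-parent numbered 1 with 1 mismatch, 1 with identical tags and 3 with the arithmetic mid-parent in limma, against 0 in edgeR (4 at an unadjusted p under 0.05) and 0 in DESeq2. Families past the size rule in Zhengdan 958 numbered 2 lower and 1 higher with the geometric mid-parent, against 4 and 0. Those in Lingdan 20 numbered 3 with identical tags, against 5. Those in Yuyu 22 numbered 3 with the geometric mid-parent and 3 with TMM factors, against 6. Tags called higher and lower against the mid-parent numbered 2168 and 196 in DESeq2, 21 and 1 with a read in every library, 0 and 0 at 10 CPM in edgeR (1047 at an unadjusted p under 0.05), and 0 and 0 with the arithmetic mid-parent in limma (2973 at an unadjusted p under 0.05). Fewer tags were tested in the settings with a read in every library and at 10 CPM.

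Size-class differences in points turned with distinct tags, to -0.479 at 20 nt and -0.544 at 23 nt. At 23 nt the difference was -0.0198 without miRNA reads and -0.234 in the libraries with tags up to 44 nt. In those libraries 5S rRNA was at -0.00247 and tRNA-Ala at -0.0215.

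Shares of parental tags with a read in the own hybrid moved most for 87-1 tags in Yuyu 22, from 96.8% (95.7% to 97.7%) to 89.3% (84.6% to 92.9%) with 21-nt tags. At 10 RPM the shares were 99.3% for Chang 7-2 and 100% for Zheng 58 in Zhengdan 958, 100% for Chang 7-2 and 99.9% for 9058 in Lingdan 20, and 98.7% for 87-1 and 99.6% for Zong 3 in Yuyu 22. Without thinning they were 100% for Zheng 58 and 99.8% for 9058. With 24-nt tags they were 97.0% for Chang 7-2 in Zhengdan 958, 99.2% for 9058, 98% for 87-1 and 97.0% for Zong 3. With 21-nt tags they were 99.7% for Zheng 58, 99.4% for Chang 7-2 in Lingdan 20 and 97.9% for Zong 3. With 22-nt tags they were 99.8% and 99.9% for Chang 7-2 in Zhengdan 958 and Lingdan 20, 100% for Zheng 58, 98.8% for 87-1 and 99.3% for Zong 3. Tags in neither parent made up 0% in Zhengdan 958 and 0.0125% in Yuyu 22 at 10 RPM. With 24-nt tags they made up 0.143% in Zhengdan 958 and 0% in Lingdan 20. With 21-nt tags they made up 0.140% and 0.331% in these hybrids. With 22-nt tags they made up 0.0136% in Zhengdan 958, 0% in Lingdan 20 and 0.203% in Yuyu 22.

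Leaving out each library in turn gave these ranges. In the mid-parent fits a left-out library takes its trios out of the estimate, and without Chang 7-2 only the Yuyu 22 trio informs it. Against inbred lines, miR156 ran from -0.24 to 0.048, miR319 from -0.066 to 0.56, miR167 from -0.22 to 0.13 and miR393 from -0.53 to 0.39. Against the mid-parent, miR319 ran from -1.28 to 1.48, miR166 from -0.24 to 0.48, miR167 from -0.23 to 0.34, miR393 from -0.75 to 0.74, miR397 from -0.20 to 0.52 and miR827 from -0.12 to 0.45. The mean of the developmental list ran from -0.21 to 0.042. Tags called higher ran from 76 to 9497 and tags called lower from 1 to 73, with the lowest counts without Chang 7-2. Size-class differences ran from -1.54 to 1.02 points at 20 nt, from -3.41 to 0.766 at 22 nt and from -0.569 to 0.470 at 23 nt. Structural RNA differences ran from -0.279 to 0.478 points for 5.8S rRNA, from -0.147 to 0.127 for 5S rRNA, from -0.0126 to 0.0408 for tRNA-Gly, from -0.317 to 0.282 for tRNA-Ala, from -0.0598 to 0.0520 for tRNA-Asp and from -0.650 to 0.787 for all together.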

Other observations

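The 5′ base of the tags differed by length, as is known for plant Argonaute proteins, which sort small RNAs by that base. Over the 8 libraries, 60.5% ± 9.66 of 24-nt reads (SD, n = 8) began with A and 59.7% ± 7.04 of 21-nt reads began with U. Of the 22-nt reads 53.8% ± 8.65 began with U and 22.7% ± 2.17 with A. In the 23-nt reads no base led clearly, with 29.9% ± 2.75 A, 31.2% ± 6.39 U and 27.4% ± 5.84 G.

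Tags below the arithmetic mid-parent by a factor of 2 or more in all 3 trios numbered 134, and tags above it numbered 7. These counts come from no test and were looked at after the data were seen. Of the 134, 99 (73.9%) were 21 nt long, against 11.4% of the 142313 tested tags, and 4 belonged to miR528 by the 16-base core. Further tags of the 134 begin like miR528 but depart from it at the last base of that core. They were not counted, so 4 is a minimum. In 75.4% of the 134 the maternal line exceeded the paternal line in all 3 trios, and in 7 tags the paternal line did. Among all tested tags these shares were 12.7% and 12.3%. The filter before testing asked for enough reads in at least 3 libraries. A tag nearly absent from the hybrids could pass it through the 3 maternal lines, but not through the 2 paternal lines alone. The excess with higher maternal lines can therefore come from the filter, and the shares of all tested tags do not correct for this. Of the tags with the higher maternal lines, 86 were 21 nt long. Their median level was 2.59 RPM over the 3 maternal lines, 0.162 over the 2 paternal lines and 0.0567 over the 3 hybrids. An example chosen after its values were seen is AACAATGACGGTATCTGAGGA, with 9.05 RPM in Zheng 58 and 20.3 in Zong 3 but 0.109 in Zhengdan 958 and 0.090 in Yuyu 22. This example overlaps in sequence with other tags of the 134, so the counts of tags may not be counts of separate small RNAs. The 134 were not compared with structural RNA beyond the 5 listed sequences. Pieces of other such RNA may therefore be among them, the example included. No explanation was tested.

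Of the 13 Yuyu 22 tags without a read in either parent, GAGGAGATGTATCGTAGAGTT had the most reads, 145, and it had no read in the other 7 libraries after thinning.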
